A study of Mus musculus with 2 samples.

How the data were processed

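Total RNA of mouse small-intestinal organoids was measured on 2 dual-colour Agilent whole-genome arrays, per the labels. RNA was isolated with RNeasy kits, amplified with T7 RNA polymerase in the presence of Cy3- or Cy5-labelled CTP and given spike-in controls, per the labels' protocols. The deposited scanner output holds spot intensity values in the green (Cy3) and red (Cy5) channels, as median pixel brightness of the spot and of its local background, with no normalization, per the file headers. It was made with Agilent Feature Extraction 10.5.1.1 on an array design built on mouse build mm9, per the file headers, while the submitters' processing notes name version 8.5.1.1 of that software. The deposited log10 ratios of red over green were background-subtracted and dye-normalized by the same software, per the file headers. The series matrix deposited by the authors holds those log10 ratios, with the sign of array 1 turned so that both columns run as RankL over untreated. Its values differed from the scanner files by at most 5.0e-06, with a median of 0 in both columns, so scale, centring and direction were settled from the values, and the authors' direction is the one used here. Flags of 0 or 1 per spot mark signals well above background, saturated spots and outliers.

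Both arrays lay on 1 slide, so no slide or scan batch could be tested. RankL was in Cy3 on array 1 and in Cy5 on array 2, per the labels. As the second array is labelled the dye swap of the first, the arrays were taken as 1 replicate of 1 RNA pair. No column of the value tables was left unused.

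Background was corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3. The design fixed before the data were examined named the mean spot signal, but the files used here gave the median, so the median spot signal was used with the median local background. Ratios were normalized within each array by loess, with the 1639 control spots of 45018 at weight 0. Control spots and spots flagged as outliers (246 on array 1, 231 on array 2) were left out, and 0 spots were saturated. Spots of 1 probe were averaged, since 245 probes were printed 10 times and 40929 once. Each ratio was turned to RankL over untreated and the arrays were averaged. Median spot signal and background were 46 and 23 for RankL and 133 and 114 for untreated RNA on array 1, and 133 and 113 for RankL and 48 and 23 for untreated RNA on array 2. Spike-in log ratios had a slope of 0.929 and 0.928 on their expected values. Over 115 measured probes printed 10 times, the median SD between spots was 0.141 and 0.154 on the log2 scale. The median SD between arrays over genes was 0.148 and its 90th percentile 0.382.

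A probe counted as measured if it was well above background in the RankL RNA on both arrays or in the untreated RNA on both (for repeated probes, in at least 0.5 of the spots), which held for 16458 of 41174 probes (40.0%). The scanner files as used here carry no gene symbols, so names came from RefSeq accessions matched without version to a table of the mouse assembly GRCm38.p6. Names were found for 26918 probes (65.4%), and 14256 kept their accession or identifier. As the array design uses another build, no coordinates are printed. A gene took the value of its measured probe with the highest mean intensity. Among 2968 genes with several measured probes, those of 2 genes, Gpd1 and Grn, disagreed in sign beyond 0.5.

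The size rule called a gene higher or lower if its mean log2 ratio was at least 1 in size, that is 2-fold, and at least 0.5 in the same direction on each array. With 1 replicate there was no test. For genes not well above background in 1 RNA on both arrays, bounds were computed per channel after loess and Aquantile normalization, with the lowest signal well above background as the floor, or the probe's own signal where higher. Each "at least" fold holds for this setting only, and another setting can read below it. Normexp's offset compresses ratios. In data simulated on these 12877 genes, 50 genes raised by 1.5 on the log2 scale were read at a median of 1.22 and 70.0% were called, 50 lowered by 1.5 were read at -1.15 and 68.0% were called, and all genes raised or lowered by 2.5 were called, at medians of 1.88 and -1.86. Of 12677 unchanged genes 0 were called. The simulated noise was set by hand and not taken from these arrays, so the 0 calls are not their error rate. These figures cover such noise between arrays, not between cultures.

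Gene lists of cell types and pathways, 26 in all, were fixed before the data were examined. A list's counts and medians cover its measured members only, unless stated otherwise, so genes dim in both RNAs are left out. Each list's median was placed among the medians of 10000 random lists of the same size matched on mean intensity in 20 bins, as a description of these arrays. Named genes followed a rule fixed at the same time. It took the 12 highest and 8 lowest genes with a symbol that met the size rule and were well above background in both RNAs on both arrays, the 6 highest and 3 lowest bounds, every measured M cell gene and up to 4 members of each other list with the largest ratios in size. Single values of some genes that the rule takes are not reported here. Of the M cell list, 6 genes stand in another list too, as do 8 of the chemokine list, 4 of the NF-kB target list and 4 each of the stem cell and Wnt target lists. The alternatives tried were no background correction, an offset of 16, the scanner software's ratio, the series matrix, median centring, both a looser and a stricter filter on dim probes, a mean over probes, each array alone and no rule on the single arrays. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.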

Results

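Gene expression was compared between small-intestinal organoids of wild-type mice that were cultured with RankL and organoids cultured without it. Organoids are epithelial structures grown from intestinal crypts in a gel, here in a medium with EGF, Noggin and R-spondin. RankL is the cytokine that binds the receptor RANK (Tnfrsf11a), which signals through NF-kB. The series' title places the comparison in a study of M cells, the antigen-sampling cells of the epithelium over Peyer's patches, and of the transcription factor Spib. Recombinant RankL was used at 50 to 200 ng/ml with fresh medium on day 2 and day 5. The exact dose and harvest time of these RNAs are not given in the sources used here.

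The data were 2 dual-colour arrays on 1 slide, and the second was labelled as the dye swap of the first. RankL RNA was in Cy3 on array 1 and in Cy5 on array 2. The arrays therefore hold 1 RNA pair, which is 1 replicate per group, so no statistical test was made and no p-value is given. Each value below is a mean log2 ratio of RankL over untreated, and its ± is the SD of the 2 arrays, a technical error that leaves out the spread between cultures. Of 43379 non-control spots, 38.3% (RankL, Cy3) and 39.6% (untreated, Cy5) were well above background on array 1, and 43.4% (RankL, Cy5) and 40.1% (untreated, Cy3) on array 2. The probes well above background in at least 1 of the RNAs on both arrays covered 12877 genes or accessions, 10401 of them with a gene symbol. The 1 RNA per condition limits the precision, since both arrays hold the same RNA pair.

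The main question was which transcripts differed between RankL-treated and untreated organoids. All 19 genes of an M cell list and 11 of 13 measured NF-kB target genes were higher with RankL, by medians of 3.40 and 2.18, while Ces2a, Spink1 and Fabp1 were among the genes farthest lower. A total of 704 genes were at least 2-fold higher with RankL and 322 at least 2-fold lower, which was 5.47% and 2.5% of those measured. The other 11851 genes (92.0%) did not meet the size rule. Differences of at least 3 on the log2 scale were seen in 67 genes that were higher and 10 that were lower. With the dye-swap sign left unturned, a measure of dye bias and noise alone, 0 genes met the same rule. Pearson's r between the arrays' turned ratios was 0.879 and Spearman's rho 0.696 across genes, which are not independent replicates. The SD over genes was 0.645 for the mean ratio and 0.164 for the part of the ratio that turned sign with the dyes. The scanner software's own log ratios gave 1148 genes higher and 781 lower.

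**Figure D1:**
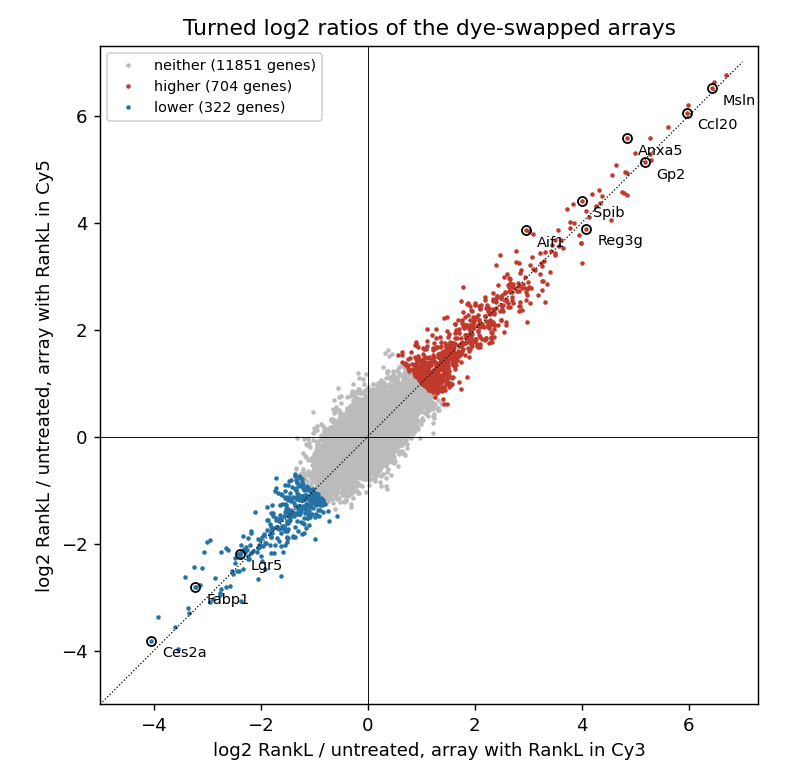
Log2 ratio of RankL over untreated on the array with RankL in Cy3 (x axis) against that on the array with RankL in Cy5 (y axis), 1 point per gene; red, blue and grey points are the 704 genes higher, 322 lower and 11851 neither by the size rule. Circled genes are named, and the dotted line marks equal ratios; Msln lies at the upper right, at 6.47 in the mean, and Ces2a at the lower left, at -3.93.

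Among genes well above background in both RNAs, the highest ratio belonged to Msln, which encodes the cell-surface glycoprotein mesothelin, at 6.47 ± 0.051 or 88.7-fold. The chemokine genes Ccl6 and Ccl9 were higher by 5.70 ± 0.13 and 4.88 ± 0.11. Fut7, a fucosyltransferase that makes selectin ligands, was higher by 5.42 ± 0.21. Ncf4, a subunit of the phagocyte NADPH oxidase, was 5.28 on each array. Pglyrp2, an amidase that cleaves bacterial peptidoglycan, was at 5.24 ± 0.089, although a second probe of the gene read 1.52. Anxa5, a phosphatidylserine-binding protein, was at 5.21 ± 0.52 and Gp2, the M cell receptor for bacterial FimH, at 5.15 ± 0.043. The secreted nuclease gene Dnase1 followed at 5.15 ± 0.21, the ubiquitin-like modifier Ubd at 4.86 ± 0.31, the enolase Eno3 at 4.68 ± 0.24 and the prion protein gene Prnp at 4.67 ± 0.16.

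Another 141 genes met the rule upwards but were not well above background in untreated RNA on either array, so only a bound holds for them. The bounds set the RankL signal against the lowest signal called well above background, or the probe's own signal where that was higher. Each bound is of 1 probe, and where the probe's own signal was used, as for ccdc198, Plekhs1 and Cubn, it equals the measured ratio. The bounds were largest for ccdc198, at least 105.5-fold, and Bcl2a1b, an inhibitor of apoptosis, at least 89.6-fold. Plekhs1 was at least 26.5-fold higher by its brightest probe, while a second probe read 1.81 on the log2 scale. Cubn, the endocytic receptor cubilin, was at least 22.1-fold higher, Xlr5a at least 19.4-fold and the potassium channel gene Kcna1 at least 19.1-fold. Bcl2a1b and Xlr5a have near-identical copies that the same probes may bind, and their values are uncertain for single genes.

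Among the genes lower with RankL, the carboxylesterase genes Ces2a and Ces1f stood at -3.93 ± 0.16 and -3.65 ± 0.39. These enzymes hydrolyse esters of drugs and lipids, and their probes too can share signal between related genes. Spink1, a trypsin inhibitor, was at -3.76 ± 0.30, and Gas6, a ligand of the TAM receptor kinases, at -3.59 ± 0.031. The carbonyl reductase Cbr3 was at -3.32 ± 0.028, the serine protease gene Prss12 at -3.28 ± 0.11, the fatty acid binding protein gene Fabp1 at -3.02 ± 0.29 and the acyl-CoA thioesterase Acot1 at -3.02 ± 0.091. Of 16 genes that were lower and not well above background in RankL RNA, the largest bounds were for the cytochrome P450 gene Cyp3a25 (at least 3.81-fold lower, with a second probe at -0.69 on the log2 scale), the interferon lambda receptor Ifnlr1 (at least 2.77-fold lower) and Agr3 (at least 2.65-fold lower).

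The series' titled question concerns M cells, and a list of 19 M cell genes was fixed before the data were examined. All 19 were measured and all 19 were higher by the size rule, with a median of 3.40 (3.34 on array 1 and 3.85 on array 2). That median lay at percentile 100 of 10000 random lists matched on intensity, whose central range ran from -0.20 to 0.24. Part of the list was known from the study of these organoids, so its count is not independent evidence of direction. Spib, the Ets transcription factor that M cells need, was at 4.21 ± 0.28, or 18.5-fold. Besides Ccl6, Ccl9, Anxa5, Gp2 and Prnp, the chemokine Ccl20 was at 6.0 ± 0.060, with untreated RNA above background on 1 of 2 arrays. Gjb2, a gap junction protein, was at 3.84 ± 0.090, with a second probe at 0.72, and Tnfaip2 was at 3.71 ± 0.21. Aif1, an actin-binding protein, was at 3.40 ± 0.64, with a second probe at 1.73, the cathepsin Ctsh at 3.29 ± 0.014, Cxcl16 at 2.92 ± 0.57, Clu at 2.83 ± 0.19, Marcksl1 at 2.58 ± 0.0088, with a second probe at 1.91, and Pglyrp1 at 1.60 ± 0.15. Tnfrsf11b, which encodes the RankL decoy receptor osteoprotegerin, was at 3.10 ± 0.34, with untreated RNA above background on 1 of 2 arrays. Sox8, Anxa10 and Scg5 were not above background in untreated RNA and were at least 5.22-fold, 4.23-fold and 3.95-fold higher, and a second Sox8 probe read 1.49 on the log2 scale. The scanner software's log ratios gave a median of 4.98 for the list.

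Genes of NF-kB signalling were next. Of 13 measured NF-kB target genes, 11 were higher, 0 lower and 2 neither, with a median of 2.18 at percentile 100 of the random lists. Rel, Cxcl1, Cxcl2 and Cd40 of the 18 fixed genes had probes but were not measured, and the median was 1.82 with dim probes included. The inhibitor genes Nfkbia, Tnfaip3 and Tnip1 were at 2.87 ± 0.15, 2.72 ± 0.12 and 2.40 ± 0.0031, and Nfkb2, the precursor of p52, at 2.75 ± 0.29. The measured members that did not meet the rule were Sod2 at -0.19 and Tnf, which was dim in untreated RNA and at least 1.43-fold higher. Traf5, Traf6 and Map3k7 of the 12 fixed components of the RANK pathway had probes but were not measured. Of the 9 measured, 2 were higher and 7 neither (median 0.55, percentile 99.54). Those higher were Map3k14, the NF-kB inducing kinase, at 2.38 ± 0.26 and the adaptor Traf2 at 1.13 ± 0.16. The receptor Tnfrsf11a was at 0.93 ± 0.17 and Traf3 at 0.82 ± 0.0017, short of the rule, though Tnfrsf11a read 1.08 with an offset of 16 and 1.29 with the scanner software's ratios. The list median ran from 0.27 to 0.77 over the alternatives. Genes of the osteoclast programme, the best-known response to RankL in another cell type, gave 0 higher and 0 lower of 4 measured out of 12 (median -0.23, percentile 10.7, and from -0.46 to 0.039 over the alternatives), with Acp5 at -0.71 ± 0.33, Fos at -0.46 ± 0.095, Nfatc1 at 0.16 ± 0.094 and Oscar at -0.0059 ± 0.0069. Ctsk, Mmp9, Calcr, Dcstamp, Atp6v0d2, Itgb3, Mitf and Tcirg1 had probes but were not measured, so the median says little about the programme.

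**Figure D2:**
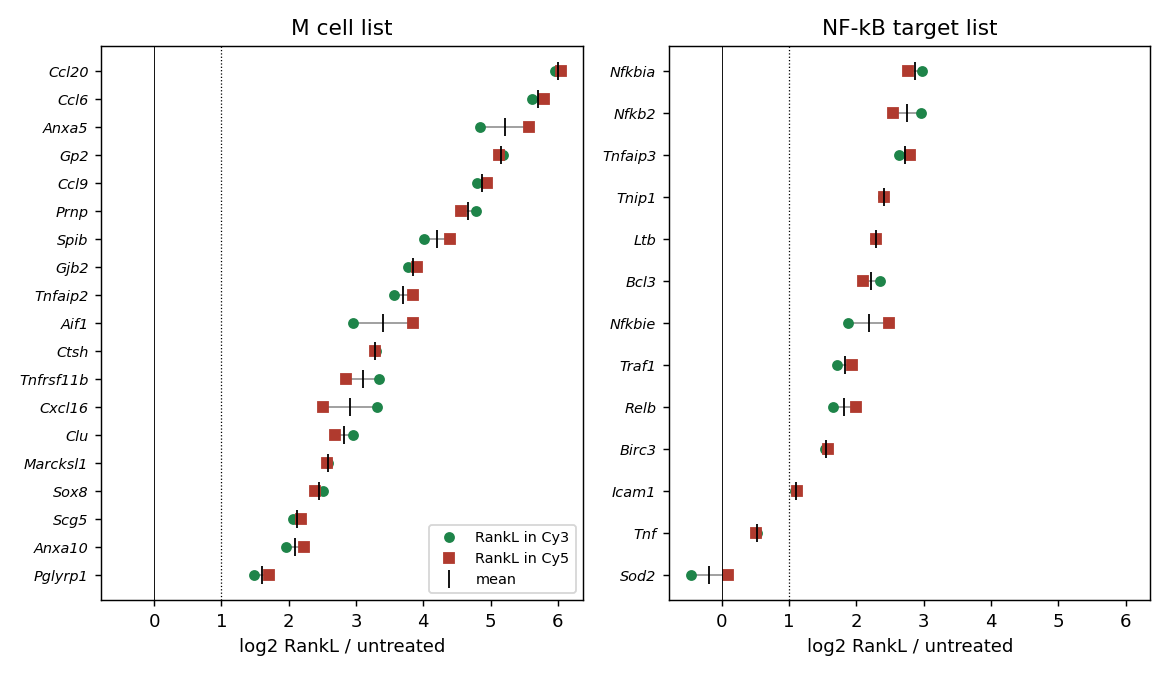
Log2 ratio of RankL over untreated (x axis) of each measured gene (y axis) of the M cell list (left) and the NF-kB target list (right), with RankL in Cy3 (circles) and in Cy5 (squares), and their mean (ticks); the dotted line marks 1. All 19 M cell genes and 11 of 13 NF-kB targets meet the size rule upwards; 3 genes of each list were dim in untreated RNA and are drawn at their measured ratios, not at their bounds.

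Of 14 measured chemokine and cytokine genes, 7 were higher, 1 lower and 6 neither, with a median of 1.01 at percentile 100, or 0.88 with bounds in place of values for genes dim in 1 RNA. Ccl20, Ccl6, Ccl9 and Cxcl16 had the largest ratios, and these belong to the M cell list too. The list median was 2.83 with the scanner software's ratios, 2.28 over the 7 members above background in both RNAs and 0.49 with dim probes included. H2-Aa, H2-Ab1, Ciita and Tap1 of the 12 fixed antigen presentation genes had probes but were not measured. Of the 7 measured, 3 were higher and 4 neither (median 0.77, percentile 99.75, and 0.43 with dim probes included). They were Cd74, the MHC class II invariant chain, at 3.23 ± 0.051, Tapbp at 1.55 ± 0.0075, with a second probe at 0.37, and the immunoproteasome subunit Psmb8 at 1.04 ± 0.18, while B2m was at 0.77 ± 0.062. In the interferon response list, 1 of 4 measured genes was higher (median 0.73, percentile 98.75, and from 0.062 with dim probes included to 1.12 with the software's ratios). Oasl2 was at least 7.46-fold higher, and Irf7 and Irf1 were at 0.74 ± 0.23 and 0.71 ± 0.038.

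Markers of the intestinal stem cell did not share a direction. Of 10 measured genes of the Lgr5 stem cell list, 1 was higher, 3 lower and 6 neither, with a median of -0.37 at percentile 0.67. Lgr5, the R-spondin receptor that marks crypt base stem cells, was at -2.30 ± 0.14, Smoc2 at -1.48 ± 0.092 and Cdca7 at -1.02 ± 0.059. Tnfrsf19 was higher at 3.12 ± 0.011, and the stem cell transcription factor Ascl2, named after its value was seen, was at 0.072 ± 0.033. The scanner software's ratios gave a list median of -0.78. Of 10 Wnt target genes, 0 were higher, 3 lower and 7 neither (median -0.46, percentile 0.07). Besides Lgr5, which both lists hold, these were Myc at -1.03 ± 0.082, whose smallest probe value was -0.49, and Ephb2 at -1.18 ± 0.33, whose second probe read -0.32. Cd44 was at 0.80 ± 0.057. In the cell cycle list, 0 of 17 genes met the size rule, but 16 lay below 0 and the median was -0.48 (percentile 0.02), with Ccna2 at -0.78 ± 0.48, Mcm3 at -0.74 ± 0.26, Mcm6 at -0.63 ± 0.46 and Ube2c at -0.63 ± 0.24.

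Enterocyte genes were higher more often than lower. Of 21 measured, 8 were higher, 3 lower and 10 neither, with a median of 0.52 at percentile 100, and of 0.20 with median centring in place of loess. The brush border peptidase Anpep was at 2.81 ± 0.23, the apolipoprotein Apoa4 at 2.57 ± 0.59 and the keratin Krt20 at 2.40 ± 0.30, against -3.02 ± 0.29 for Fabp1. The other genes lower were Dpp4 at -1.89 ± 0.077 and Cyp3a11 at -1.41 ± 0.046, both named after their values were seen, to complete the count of 3.

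Secretory cell markers were mixed. Of 5 measured Paneth cell genes out of 10, 2 were higher, 1 lower and 2 neither (median 0.24, percentile 84.4, and 0.13 on array 2 alone). The metalloproteinase Mmp7 was at 3.12 ± 0.13, lysozyme (Lyz1) at 1.46 ± 0.15, the lectin Itln1 at -1.71 ± 0.12 and Wnt3 at 0.24 ± 0.15. Of 9 goblet cell genes, 3 were higher, 2 lower and 4 neither. Their median was -0.30 (percentile 2.77, and -0.14 on array 2 alone) while their mean was 0.066, opposite in sign. Fcgbp and Zg16 were at 1.92 ± 0.25 and 1.89 ± 0.18, and Spink4 and Agr2 at -2.11 ± 0.17 and -1.58 ± 0.058. Of 13 enteroendocrine genes, the hormone genes Sct (2.08 ± 0.019) and Cck (1.04 ± 0.31) were higher and 11 were neither, with Pyy at -0.93 ± 0.18 (a second probe at -0.39) and Nts at -0.83 ± 0.072 (median 0.14, percentile 85.8, and from 0.0025 to 0.18 over the alternatives). Cck read 0.82 on array 1 and 1.26 on array 2, so it fell short of 1 on array 1 alone. Of 7 tuft cell genes, 1 was higher and 6 neither (median 0.67, percentile 99.9, and from 0.39 with dim probes included to 1.03 with the software's ratios). It was Gfi1b at 2.93 ± 0.66, with untreated RNA above background on 1 of 2 arrays, while Trpm5 and Dclk1 were at 0.89 ± 0.062 and 0.77 ± 0.078, and Ptgs1, dim in untreated RNA, was at least 1.59-fold higher.

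Antimicrobial genes that respond to microbes diverged within 1 gene family. Reg3g, a C-type lectin that kills Gram-positive bacteria, was higher at 3.98 ± 0.15, Reg3a was lower at -2.37 ± 0.16 and Reg3b was at 0.77 ± 0.20. Pigr, the receptor that carries IgA across the epithelium, was lower at -2.61 ± 0.63. Of 7 members measured, 1 was higher, 2 lower and 4 neither, with a median of -0.50 at percentile 0.20, which turned to 0.022 when dim probes were included and was -0.24 over the 6 members above background in both RNAs. Of 15 lysosome genes, 5 were higher, 1 lower and 9 neither (median 0.29, percentile 96.9, and 0.16 with median centring). Besides Ctsh, those higher included Ctsl at 1.36 ± 0.49 and Cd63 at 1.34 ± 0.26.

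**Figure D3:**
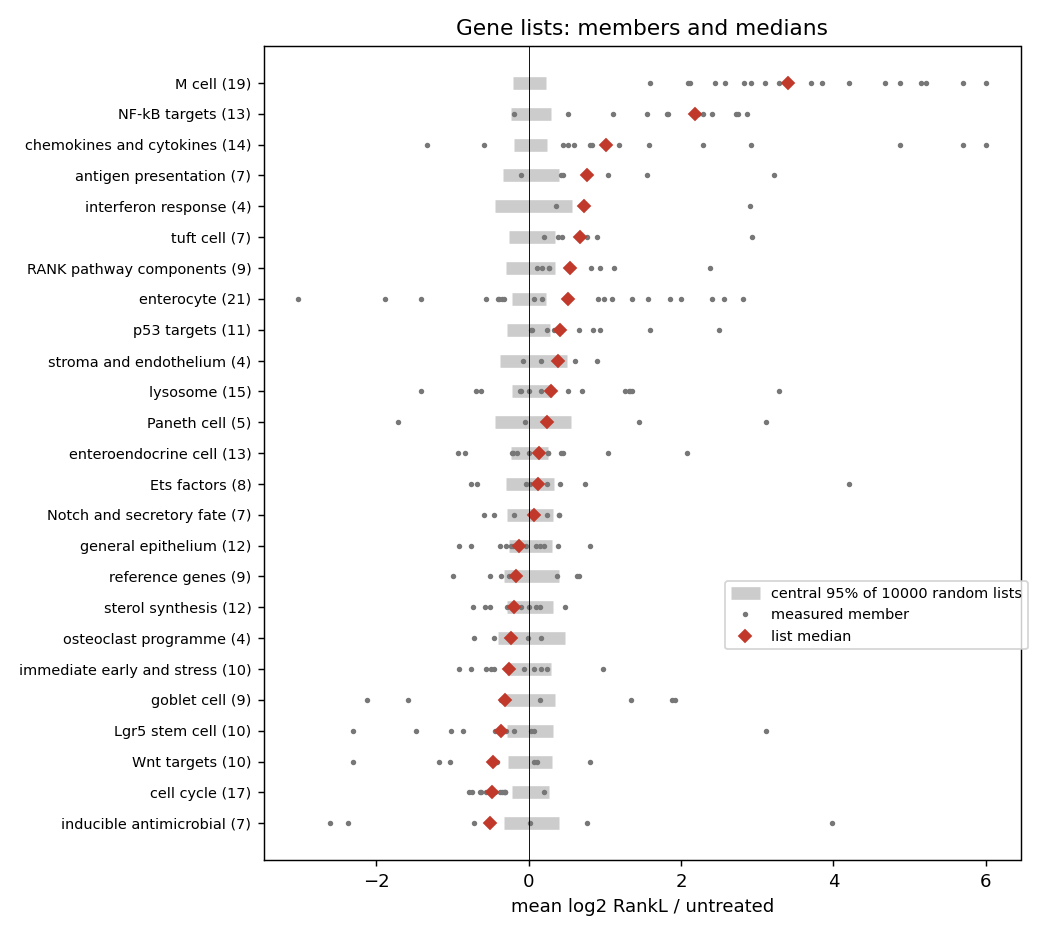
Median log2 ratio of RankL over untreated (x axis, diamonds) of each gene list with at least 3 measured genes (y axis, number measured in brackets), with each measured gene (grey dots) and the central 95% of the medians of 10000 intensity-matched random lists (grey bars). The M cell median of 3.40 and the NF-kB target median of 2.18 lie farthest from their random range.

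Of 11 p53 target genes, Pmaip1 (2.49 ± 0.035) and Trp53inp1 (1.59 ± 0.0030, with a second probe at 0.81) were higher and 9 neither, with Phlda3 at 0.94 ± 0.062 and Cdkn1a at 0.85 ± 0.25 (median 0.41, percentile 99.47, and 0.66 with the scanner software's ratios). Of 8 Ets factor genes, Spib was higher and 7 were neither (median 0.13, percentile 78.9, and from -0.027 to 0.20 over the alternatives), among them Elf3 at -0.75 ± 0.13, Ehf at -0.67 ± 0.13 and Elk3, which was dim in untreated RNA and at least 1.67-fold higher, with a second probe at 0.19 on the log2 scale. No member of the remaining lists met the size rule in the main setting, but with the scanner software's ratios Hes1 read -1.33, Hes5 -1.21, Egr1 -1.27, Atf3 -1.52 and Xbp1 -1.03. The 7 measured genes of Notch and secretory fate had a median of 0.069 (percentile 70.3) but a mean of -0.016, and the median ran from -0.0027 to 0.10 over the alternatives, with Hes1 at -0.58 ± 0.040, Hes5 at -0.46 ± 0.058, Notch2 at 0.40 ± 0.029 and Dll1 at 0.40 ± 0.13. The 12 sterol synthesis genes had a median of -0.19 (percentile 8.32, and from -0.32 to -0.11 over the alternatives), with Lss at -0.73 ± 0.016, Sqle at -0.57 ± 0.17, Insig1 at -0.51 ± 0.10 and Hmgcs1 at 0.48 ± 0.12, with a second probe at -0.060. The 10 immediate early and stress genes had a median of -0.26 (percentile 3.20, and from -0.42 to -0.063 over the alternatives), with Junb at 0.98 ± 0.058, Egr1 at -0.91 ± 0.21, Xbp1 at -0.76 ± 0.10 and Atf3 at -0.56 ± 0.14, with RankL RNA above background on 1 of 2 arrays.

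Genes of cells outside the epithelium were mostly not well above background. Of 12 leukocyte genes with a named probe, Coro1a was well above background in RankL RNA on both arrays, at 0.50 ± 0.016 with untreated RNA above background on 1 of 2, and 0 were in untreated RNA on both. Of 13 genes of stroma and endothelium, 4 were well above background in RankL RNA on both arrays and 3 in untreated RNA, and none of the 4 measured met the size rule (median 0.39, percentile 94.8, and 0.027 with dim probes included). Pdgfrb, dim in untreated RNA, was at least 1.87-fold higher, Acta2 was at 0.62 ± 0.036 (a second probe at -0.087), Col1a2 at 0.17 ± 0.17 and Vim at -0.067 ± 0.0077. Of the 12 general epithelial genes, 0 met the rule (median -0.12, percentile 14.8, and from -0.30 with median centring to -0.0098 with the software's ratios), with Krt18 at -0.92 ± 0.29, Vil1 at 0.81 ± 0.075 and Cldn3 at 0.39 ± 0.21. The 9 reference genes measured did not meet it either (median -0.17, percentile 14.8, and from -0.48 with median centring to -0.063 with the software's ratios), with Pgk1 at -0.99 ± 0.099, Actb at 0.66 ± 0.052, Ywhaz at 0.64 ± 0.060 and Sdha at -0.51 ± 0.14. With median centring, Pgk1 and Krt18 read -1.28 and -1.29, past 2-fold in size.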

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

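The 11 alternatives were planned before the data were examined. Every one of the 80 named genes that met the size rule kept its direction in each setting (64 could be computed where both RNAs had to be above background), and 77 to 80 stayed at least 1 in size. On each array alone the direction was fixed in advance, since the rule requires it on both arrays. With either filter on dim probes the median ratio to the main value was 1, so these settings say little about direction either. The counts of genes higher and lower stayed within 1.5 times of 704 and 322 except with the scanner software's log ratio and the series matrix, which hold the same values and gave 1148 higher, 781 lower, 1 gene with the sign unturned, r = 0.9187 between arrays and an M cell median of 4.984. Of the genes called there, 59.5% were higher, against 68.6% in the main setting and 61.1% with median centring (610 higher, 389 lower). Without background correction, 1 gene met the rule with the sign unturned and r was 0.8571. The correlation was 0.874 with an offset of 16, 0.8746 with median centring, 0.8883 with the mean over probes, 0.8054 with no filter on dim probes and 0.8588 with both RNAs above background. The M cell median was 3.775 over the 14 genes above background in both RNAs and 3.853 on the array with RankL in Cy5 alone. The antimicrobial list's median was reversed to 0.02184 with no filter on dim probes, which takes in 13 members in place of 7. The same setting turned the sign of 3 medians that lay inside their random ranges, to 0.039 for the osteoclast list, -0.027 for the Ets factors and -0.0027 for the Notch list. The larger M cell median with both RNAs above background comes from leaving out dimmer members. The cause was not tested for the others. Over the 25 lists other than the M cell list, 145 medians under an alternative moved by less than the SD of the arrays, and the rest moved by more, 4 of them with a change of sign, as given above. Of 51 named genes short of the size rule, 0 changed sign, but 20 reached 1 in size in at least 1 setting, 16 of them with the scanner software's ratios and 9 with an offset of 16. Median centring and the software ratio moved the median of all genes by less than 0.1. No paired analysis was possible because there is 1 RNA pair. Signal over background limits the folds of dim genes, since 141 of 704 higher and 16 of 322 lower genes have only a bound.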

Other observations

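The gene groups by name, the tests of explanations and the single genes named in the opening paragraphs were chosen after the values were seen, while the gene lists and processing settings that they draw on were planned. A scan of 327 groups of at least 5 measured genes that share the stem of their symbol placed 13 in the lowest 0.5% and 7 in the highest 0.5% of intensity-matched random lists. About 3.27 in all would be expected by chance if the genes of a group varied independently, which related genes need not do. The groups are defined by name alone, and no theme across them was tested. All 13 low medians stayed below 0 and all 7 high medians above 0 in 4 other background and normalization settings. Of 13 carboxylesterase genes (stem Ces), 6 were lower and 3 higher with a median of -0.95, so the family was split. Of 45 cytochrome P450 genes (Cyp), 13 were lower and 4 higher with a median of -0.50. Of 9 glucuronosyltransferase genes (Ugt), 4 were lower and 0 higher (-0.68), of 15 aldehyde dehydrogenase genes (Aldh), 4 were lower and 1 higher (-0.45), and of 7 glutathione transferase genes of the mu class (Gstm), 3 were lower and 0 higher (-0.68). Gsta1 and Gstm3 were at -2.97 ± 0.099 and -2.96 ± 0.26. Of 7 kallikrein genes (Klk), 4 were lower and 0 higher (-1.15). With the scanner software's ratios the medians of Ces, Cyp, Ugt, Gstm and Klk were larger in size, at -1.94, -0.76, -2.62, -1.35 and -2.83. The Rpl and Rps stems were low too, at -0.35 over 46 genes and -0.36 over 39. Both stems depended on the setting, at -0.71 and -0.67 with median centring and -0.24 and -0.16 with the scanner software's ratios. Outside the ribosomal protein set used later they held 11 genes, among them Rps6kl1 at 3.89 ± 0.17, which was higher, and Rps4l at -1.05 ± 0.021, which was lower. The other low groups were Ifi, Camk, Fzd, Galnt and Cep, at -0.89, -0.47, -0.46, -0.45 and -0.22 (Cep at -0.37 with those ratios). These families hold close paralogs that can share probe signal.

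Of 8 Serpinb genes, which encode intracellular protease inhibitors, 5 were higher and 0 lower (median 1.5), with Serpinb1a at 4.44 ± 0.083 and Serpinb6a at 4.12 ± 0.032. Of 6 Clca genes, 5 were higher (median 1.33), and of 10 TNF receptor superfamily genes (Tnfrsf), 4 were higher and 1 lower (median 0.68), with Tnfrsf4 (OX40) at 2.83 ± 0.072. Guca2a and Guca2b, which encode the gut peptides guanylin and uroguanylin, were at 3.45 ± 0.029 and 3.45 ± 0.070. The Serpinb median was 3.69 with the scanner software's ratios. The other high groups were Tnfaip, Ccl, Bmp and Cd, at 1.23, 1.03, 0.71 and 0.31, or 1.92, 2.59, 1.70 and 0.51 with the software's ratios.

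The M cell and NF-kB target lists were higher with RankL. A dye bias would turn sign between the arrays, but the lower of the arrays' turned M cell medians was 3.341. Leukocytes in the RankL culture would bring their other abundant transcripts, but 1 of 12 leukocyte genes with a named probe, Coro1a, was well above background in the RankL RNA. A difference between the cultures other than RankL stays open, since there was 1 RNA per condition and the pair cannot be told apart from chance between cultures. A response of the epithelium to RankL therefore remains a hypothesis.

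The enterocyte and stem cell lists were split within themselves. If every member were expressed more in enterocytes than in other cells, a larger share of enterocytes with unchanged expression would raise all members. Of the 21 members, 3 were lower by the size rule. A larger share alone would not give this pattern under that condition. Expression of the members in other cells was not measured, so a larger share of enterocytes stays open. A shift among kinds of enterocytes was not tested and stays open. If every marker were confined to Lgr5 stem cells, a smaller share of these cells would lower the others about as much as Lgr5. Of the 9 others, 1 was lower by at least 0.5 of the log2 ratio of Lgr5. Expression of the markers in other cells was not measured, so a smaller share of stem cells stays open. Changes in the regulation of single genes, in both cases, were not tested and stay open.

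The medians of 17 cell cycle genes and 77 ribosomal protein genes were below 0, at -0.48 and -0.39, with 0 genes of either group meeting the size rule. For the cell cycle genes the highest median over the 4 other background and normalization settings was -0.4818, against an SD between arrays of 0.039, so the sign held in these settings. All of them keep the median of all genes near 0, so they cannot test that shared centring as a cause. The 9 reference genes had a median of -0.48 with median centring, where the cell cycle median was -0.60. With the software ratio these medians were -0.063 and -0.56. For the ribosomal protein genes the highest was -0.219 (software ratio) and the lowest -0.715 (median centring), against an SD of 0.149, so the sign held but the size depended on the setting, and without background correction the arrays read -0.76 and -0.099. The ribosomal protein median lay at percentile 0 of 10000 random lists matched on intensity in bins, so it was lower than in genes of similar intensity. A trend with intensity inside the bins would not be seen this way, and the size of the median depended on the normalization. An effect of intensity on the ribosomal protein median therefore stays open. No biological explanation was tested, and 1 RNA pair leaves a difference between cultures open.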
